A study of Mus musculus with 24 samples.

How the data were processed

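The starting point was 2 tables that the authors deposited. The first table holds the authors' counts, whole reads per gene with no normalization, for 55401 genes and 7 ribosomal RNA entries. The second table, which the authors deposited as normalized counts, holds a signal: reads per gene divided by 1 size factor per library. Multiplying by that factor gave whole numbers within 6.4e-10 for all values, and the factors equal DESeq2's median-of-ratios factors. The second table also holds 92 ERCC and 22 SIRV spike-in RNAs that the first lacks, 62 of them with at least 1 read. The tables come from different read assignments, since the reads of 7689 genes differ between them. Among the 11717 genes tested, the total differed by over 10% for 593. The submitters' notes list cutadapt 1.18, FastQC, STAR 2.6.1a, featureCounts 1.6.4, Subread, DESeq2 and the GRCm38 build. The order of these tools, the strand setting, the treatment of reads with several matches and the annotation release are not given in the sources used here. The column names of the count table call the control cells "Veh", while the sample labels call them untreated; the cells are called untreated here.

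The ribosomal RNA entries were set aside. Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), libraries were scaled by TMM, and edgeR 4.0.16 fitted a robust quasi-likelihood model with 1 mean per group over all 24 libraries, leaving 18 residual degrees of freedom. Differences were tested with edgeR's quasi-likelihood F test, and p was adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05. Levels are CPM of the scaled library, as mean ± SD over the 4 libraries of a group. Log2 fold changes carry their standard error (SE), the log2 fold change divided by the square root of F. These p-values rest on a spread between libraries that is pooled per gene over all 24 libraries, not on that of the groups compared alone. Nothing in the labels says whether libraries with the same number share an animal, or whether the replicates are separate animals. The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

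Gene lists were written from textbook knowledge: 22 pathway lists, 8 lists of markers of other cell types and 1 of mitochondrial transcripts as a sign of RNA quality. Each list was tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 31 lists of a comparison. Camera was repeated with a correlation estimated per list, and every list was also tested with fry, which asks whether its members move one way on balance. Members past the gene test were counted with the adjustment over all genes and with p adjusted over the list alone.

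Genes named in the text follow a rule. For each treatment against untreated cells, it takes the 6 highest and 6 lowest called log2 fold changes among genes with at least 10 CPM in the higher group and with all 4 treated libraries on one side of all 4 untreated ones, which chance gives 2.86% of genes. It adds the 3 members of each pathway list with the largest absolute change at 10 CPM or more, and 12 index genes, among them Tnf, Il1b, Il6, Il10, Nlrp3, Cxcl10, Ifnb1, Nos2, Arg1, Tlr4 and Abca1. Some items are not reported here. For S14 against LPS and for differences between times it takes the 5 highest and 5 lowest, and for untreated cells over time the 3 highest and 3 lowest. Where the text names other genes, it says that they were chosen after their values were seen.

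Where a group had 0 counts of a gene, the fold change is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of CPM is given with its 95% counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Positions are from GENCODE M21 on GRCm38, which holds 55141 of the genes. The spike-in reads were used after the data were seen, as another scaling and as a measure of library content; the amount added to each sample is not given in the sources used here.

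Correlations between responses were taken across genes, which are not independent replicates, from differences of mean log2 CPM. The same 4 untreated libraries enter both responses at a time, which alone gives a positive correlation. The values are therefore set beside 20 simulations with unchanged treated groups. These were drawn with the untreated libraries' mean and a spread per gene pooled over all 24 libraries. The values are also set beside splits that give each treatment its own pair of controls. A check on simulated counts with the libraries' depths and spread and known changes recovered 55.2% of genes changed 1.5-fold, 64.2% at a fold of 2 and 90.9% at a fold of 4 in the S14 comparison at 3 h. In that check 4.76% of the calls were genes left unchanged. At 18 h the shares were 47.8%, 77.6% and 86.4%, with 7.24% unchanged. A list of 24 genes raised by a fold of 2 was called at 6.86e-63, and 0 of 29 unchanged lists were called by camera. Genes were simulated as independent, so this does not measure false list calls among correlated genes. For the correlation, 90.2% of a covariance placed in simulated counts was recovered.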

Results

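The mRNA of mouse bone marrow-derived macrophages was measured by 3' end sequencing, in which reads come from the 3' end of polyadenylated transcripts (QuantSeq FWD libraries from 150 ng of RNA, 15 PCR cycles, NextSeq 2000). The cells came from C57BL/6J wild-type mice and grew in medium conditioned by L929 cells, a source of the macrophage growth factor M-CSF. They were left untreated, stimulated with S14 at 30 µM, or stimulated with lipopolysaccharide (LPS) at 100 ng/mL, for 3 h or 18 h. S14 is sphingomyelin d18:1/14:0, a membrane sphingolipid with a fatty acid chain of 14 carbons. LPS is a bacterial outer membrane component that Toll-like receptor 4 recognises. Each of the 6 groups held 4 libraries, so n = 4 for every mean below. The values are the authors' whole read counts per gene. Their totals ran from 3334182 to 6350251 per library, with 13405 to 15505 genes detected and 11717 genes tested.

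The groups separated by treatment and time. The first principal component of log2 CPM held 40.3% of the variance and the second 26.8%. LPS libraries at 3 h lay highest on the first component, from 99.5 to 100.5, and S14 libraries at 3 h lay from 12.9 to 18.3, against -25.3 to -22.6 for untreated cells. At 18 h the S14 libraries lay from -42.8 to -39.9, closer to untreated cells (-54.4 to -50.8) than to LPS (2.4 to 3.6). Replicate 4 of untreated cells at 18 h stood apart from its group on the fourth component (54.17) and in its spread of log2 deviations (0.429, against 0.202 to 0.24 in the other libraries of its group). Where 2 values scaled to spike-in reads are given below, the second leaves this library out.

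**Figure D1:**
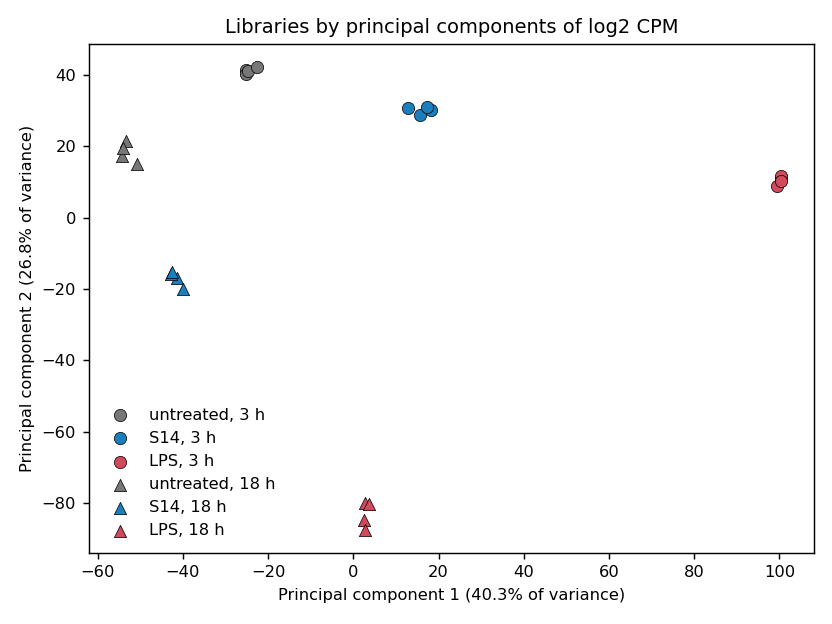
First and second principal components of log2 CPM for the 24 libraries, 1 point per library, coloured by treatment and marked by time. LPS libraries at 3 h lie from 99.5 to 100.5 on the first component and untreated ones from -25.3 to -22.6.

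All directions below are relative to the typical gene of each library, since TMM scales libraries to each other. The median log2 fold change of all genes was -0.111 with LPS at 3 h and within 0.1 of 0 in the other comparisons. Scaling to the spike-in reads instead, an alternative chosen after the data were seen, moved log2 fold changes by a median of 0.11 with S14 and 0.34 with LPS at 3 h, and of -0.97 and -0.64 at 18 h. For S14 against LPS the median shift was -0.23 at 3 h and -0.32 at 18 h, and for untreated cells at 18 h against 3 h it was 0.83. Without replicate 4 of untreated cells at 18 h, the shifts at 18 h were -0.48 with S14 and -0.16 with LPS, and that of untreated cells over time was 0.34. Spike-in reads made up 0.0268% ± 0.00624 of reads with LPS at 3 h against 0.0505% ± 0.00756 untreated (exact permutation p = 0.0286, the smallest possible, two-sided; 0.0572 adjusted over 4 comparisons). They made up 0.049% ± 0.00524 with S14 at 18 h against 0.0316% ± 0.0126 (p = 0.0286, exact, smallest possible; 0.0572 adjusted). With S14 at 3 h the exact p was 0.286 (0.381 adjusted) and with LPS at 18 h 0.571 (0.571 adjusted). Within untreated cells at 18 h the share ran from 0.0134% to 0.0418%.

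Main index genes lie, on GRCm38, as follows in GENCODE M21. Tnf (ENSMUSG00000024401) is on chromosome 17 from 35199381 to 35202007, Il1b (ENSMUSG00000027398) on chromosome 2 from 129364570 to 129371139 and Nlrp3 (ENSMUSG00000032691) on chromosome 11 from 59541568 to 59566956. Cxcl10 (ENSMUSG00000034855) is on chromosome 5 from 92346638 to 92348889, Nos2 (ENSMUSG00000020826) on chromosome 11 from 78920787 to 78960254 and Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484. Tlr4 (ENSMUSG00000039005) is on chromosome 4 from 66827584 to 66930284. Saa3 (ENSMUSG00000040026), on chromosome 7 from 46711998 to 46715700, and Marco (ENSMUSG00000026390), on chromosome 1 from 120474538 to 120505024, are named by their changes. M21 lists each as protein-coding.

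The comparison of S14 with untreated cells at 3 h asks which genes the lipid changed early. S14 raised cytokines, chemokines, interferon-stimulated genes and antimicrobial genes together. Il1b, which encodes the precursor of interleukin-1β, rose from 12.4 ± 2.63 to 503 ± 126 CPM (log2 fold change 5.35 ± 0.4, adjusted p = 3.65e-09). Tnf, the cytokine tumour necrosis factor, rose from 175 ± 17.8 to 697 ± 70.5 CPM (1.99 ± 0.09, adjusted p = 4.39e-21). Nlrp3, the sensor of an inflammasome that activates caspase-1, rose from 57.8 ± 19.4 to 179 ± 28.2 CPM (1.64 ± 0.17, adjusted p = 9.38e-09). The largest rises included Saa3, an acute-phase serum amyloid protein (1190 ± 214 against 26.9 ± 4.14 CPM, 5.47 ± 0.2), Ccl5, a chemokine for T cells (561 ± 50.4 against 15.3 ± 2.52 CPM, 5.19 ± 0.12), and Nos2, the inducible nitric oxide synthase (27.1 ± 4.23 against 0.748 ± 0.391 CPM, 5.12 ± 0.33). Il12b, a subunit of interleukin-12, had 2 reads in untreated cells and reached 11.3 ± 1.58 CPM, a ratio of 98.7 (95% counting interval 27 to 820). Il6 had 1 read in untreated cells and reached 8.26 ± 2.36 CPM, a ratio of 143 (25.4 to 5700).

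S14 changed 1786 genes at 3 h, 1060 higher and 726 lower; 380 rose and 134 fell by at least 2-fold. Among inflammatory cytokines and chemokines, 23 of 24 tested members rose (23 adjusted over the list alone), with a median log2 fold change of 2.43 (camera adjusted p = 5.94e-43). The list of NF-kB feedback regulators holds inhibitors of this transcription factor, its own subunits such as Rel, and other genes of the response. Of its 28 tested members 26 rose (27 adjusted over the list alone, median 1.1, adjusted p = 3.97e-32). They included Socs3, an inhibitor of cytokine signalling, at 3.59 ± 0.21. Of 46 interferon-stimulated genes, 42 rose (44 adjusted over the list alone, median 1.35, adjusted p = 3.72e-48), among them Cxcl10, a chemokine induced by interferons, from 277 ± 24.2 to 1730 ± 223 CPM (2.65 ± 0.18), and the guanylate-binding protein gene Gbp5 (3.44 ± 0.28). Of 20 antimicrobial effectors, 16 rose (16 adjusted over the list alone, median 2.56, adjusted p = 2.29e-22). In the list of MHC class I and costimulation, 13 of 19 rose (15 adjusted over the list alone, median 0.5, adjusted p = 2.29e-13), with the costimulatory receptor Cd40 at 2.6 ± 0.11 and the checkpoint ligand Cd274 at 2.46 ± 0.22. These 5 lists kept a positive median and no member fell when scaled to spike-in reads. Fewer members then rose, in the order given 19, 18, 30, 13 and 4. Without untreated 18 h replicate 4 they were 22, 23, 37, 14 and 8.

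Smaller shifts touched other pathways. In the inflammasome list 9 of 19 rose and 2 fell (13 called adjusted over the list alone, adjusted p = 0.000427), including the caspase gene Casp4 at 1.26 ± 0.13. In the list of the TLR4 receptor complex 13 of 23 rose and 1 fell (14 called adjusted over the list alone, adjusted p = 1.08e-05). Tlr1, a partner of TLR2 in sensing lipopeptides, rose by 1.68 ± 0.12, while Tlr4 itself fell from 80.9 ± 5.89 to 48.5 ± 4.19 CPM (-0.74 ± 0.11, adjusted p = 5.47e-07). Scaled to spike-in reads, the fall of Tlr4 was not called, with or without untreated 18 h replicate 4. Of 21 genes of the integrated stress response, an adaptation to amino acid or protein folding stress, 5 rose (5 adjusted over the list alone, adjusted p = 0.00773), led by the cystine transporter Slc7a11 at 2.87 ± 0.29. Of 23 genes of the NRF2 antioxidant programme, 8 rose and 1 fell (10 called adjusted over the list alone, adjusted p = 0.00773). That call was lost at adjusted p = 0.212 with an estimated correlation. For glycolysis and hypoxia 8 of 24 rose (9 called adjusted over the list alone, adjusted p = 0.00574, and adjusted p = 0.212 with an estimated correlation), among them Pfkfb3, which makes an activator of glycolysis, at 1.47 ± 0.15. Fewer members rose when scaled to spike-in reads. They were 3 in the inflammasome list, 3 for the TLR4 complex, 3 for the stress response, 1 for NRF2 and 2 for glycolysis. Without untreated 18 h replicate 4 they were 9, 9, 4, 3 and 5.

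Lists of lipid genes did not pass the list test with S14 at 3 h. Of 25 genes of cholesterol synthesis and uptake 4 rose (4 adjusted over the list alone, adjusted p = 0.0537). Abca1, a cholesterol exporter and LXR target, rose by 0.57 ± 0.14 (adjusted p = 0.00325), while of 17 LXR targets 2 rose and 5 fell (8 called adjusted over the list alone, adjusted p = 0.0735). Scaled to spike-in reads, no LXR target was called higher and 1 was called lower, with or without untreated 18 h replicate 4. In the list of sphingolipid metabolism, the pathway of the added lipid, 3 of 35 rose and 5 fell (8 called adjusted over the list alone, adjusted p = 0.0999). There Cers6, a ceramide synthase, rose by 1.4 ± 0.1 and Cerk, which phosphorylates ceramide, fell by 0.99 (SE 0.09). In the cell cycle list 5 of 32 fell (5 adjusted over the list alone, adjusted p = 0.0123, and adjusted p = 0.35 with an estimated correlation), with the cyclin Ccnd1 at -1.32 ± 0.16. The lowest values belonged to Rasgrp3, an activator of Ras (-1.99 ± 0.18), and Cxcr4, a chemokine receptor (-1.69 ± 0.14). With spike-in scaling 374 genes passed, 346 higher and 28 lower, or 795 with 676 higher when untreated 18 h replicate 4 was left out of the fit.

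LPS against untreated cells at 3 h serves as the reference of a strong bacterial stimulus. LPS changed 6500 genes, 2964 higher and 3536 lower, and 1582 rose and 1630 fell by at least 2-fold. Il1b reached 4010 ± 527 CPM (8.34 ± 0.43, adjusted p = 1.25e-12) and Cxcl10 reached 16300 ± 1980 CPM (5.88 ± 0.21, adjusted p = 1.23e-15). Tnf reached 879 ± 73.1 CPM (2.33 ± 0.09, adjusted p = 7.48e-25) and Nlrp3 reached 170 ± 19.7 CPM (1.56 ± 0.17, adjusted p = 3.94e-09). The anti-inflammatory cytokine Il10 rose from 5.87 ± 2.34 to 192 ± 5.19 CPM (5.02 ± 0.22, adjusted p = 1.8e-20). Il6, at 319 ± 34.5 CPM, had a ratio of 5450 (95% counting interval 979 to 216000), and Edn1, the vasoactive peptide endothelin-1, at 590 ± 14.7 CPM, a ratio of 10100 (1810 to 399000), each over 1 untreated read. Ifnb1, which encodes interferon-β, had 0 untreated reads and rose at least 66.8-fold, to 11.7 ± 5.94 CPM.

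With LPS at 3 h all 46 interferon-stimulated genes rose (46 adjusted over the list alone, median 3.92, adjusted p = 1.18e-35), as did 23 of 24 cytokines and chemokines (23 adjusted over the list alone, median 5.09, adjusted p = 3.48e-20). All 28 NF-kB feedback regulators rose (28 adjusted over the list alone, median 2.57, adjusted p = 1.42e-21), with Socs3 at 6.78 ± 0.22, and all 19 genes of MHC class I and costimulation (19 adjusted over the list alone, median 1.97, adjusted p = 1.85e-13). Of 20 antimicrobial effectors 14 rose and 2 fell (17 called adjusted over the list alone, adjusted p = 8.87e-07). In the inflammasome list 13 of 19 rose and 3 fell (16 called adjusted over the list alone, adjusted p = 0.000167), with the DNA sensor Aim2 at 3.02 ± 0.16. In the list of the TLR4 receptor complex 14 of 23 rose and 5 fell (19 called adjusted over the list alone, adjusted p = 0.00531), with the adaptor Myd88 at 2.2 ± 0.09. Tlr4 gave -0.17 ± 0.1 (adjusted p = 0.163, and -0.26, adjusted p = 0.0489, without LPS replicate 3). Of 21 immediate early genes 12 rose and 4 fell (16 called adjusted over the list alone, adjusted p = 0.0235, and adjusted p = 0.199 with an estimated correlation). Metallothionein Mt2, which binds metal ions, rose from 59.8 ± 6.68 to 3760 ± 395 CPM (5.98 ± 0.12).

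Genes of lipid synthesis, division and some receptors fell with LPS at 3 h. Of 25 genes of cholesterol synthesis and uptake 16 fell and 1 rose (18 called adjusted over the list alone, median -0.49, adjusted p = 0.00531, and adjusted p = 0.349 with an estimated correlation), with the sterol enzyme Mvd at -2.54 ± 0.19. In the cell cycle list 21 of 32 fell and 3 rose (24 called adjusted over the list alone, median -0.7, adjusted p = 0.00531, and adjusted p = 0.349 with an estimated correlation). Of 30 genes of oxidative phosphorylation 14 rose (14 adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.323 with an estimated correlation). Tfeb, a regulator of lysosome genes, fell from 24.6 ± 3.06 to 1.55 ± 1.34 CPM, and Cx3cr1, the fractalkine receptor, from 199 ± 31.8 to 22.1 ± 4.28 CPM (-3.17 ± 0.35). Cnr2, the cannabinoid receptor of immune cells, had 11.6 ± 0.562 CPM untreated and 0 reads with LPS, a fall of at least 59-fold. Under spike-in scaling 3296 genes passed, 2341 higher and 955 lower, or 4671 with 3290 higher without untreated 18 h replicate 4. The cholesterol and cell cycle medians were then -0.26 and -0.35, or -0.25 and -0.35 without it.

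**Figure D2:**
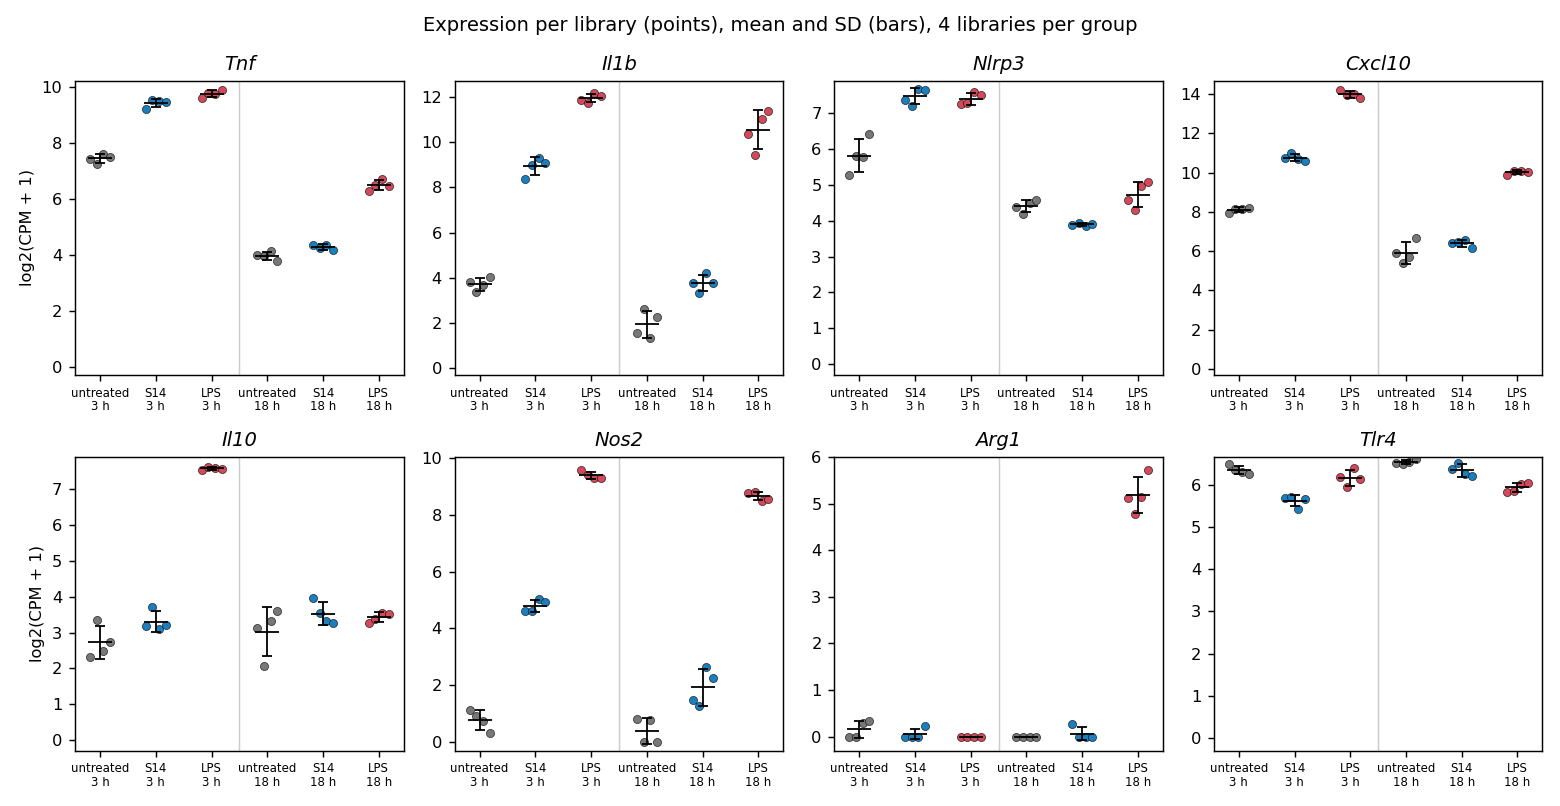
Expression of 8 index genes as log2(CPM + 1) in untreated, S14 and LPS cells at 3 h and 18 h; points are libraries, bars the mean and SD of 4. At 3 h Nlrp3 averaged 179 CPM with S14 and 170 with LPS, while Cxcl10 averaged 1730 and 16300.

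S14 and LPS were compared directly at 3 h, asking where the lipid's effect differed from that of LPS. Nlrp3 did not pass the test (0.08 ± 0.16, adjusted p = 0.725), which does not show that both act alike. The chemokine gene Cxcl2, chosen after its values were seen, was higher with S14 (751 ± 123 against 531 ± 82.8 CPM, 0.5 ± 0.13, adjusted p = 0.00305). Scaled to spike-in reads, Cxcl2 was not called higher, with or without untreated 18 h replicate 4. Tnf was lower with S14 by a log2 fold change of -0.33 ± 0.09 (adjusted p = 0.00144). Other inflammatory genes were much lower with S14: Il1b at -2.99 ± 0.31, Cxcl10 at -3.23 ± 0.19, Il10 at -4.41 ± 0.21, Nos2 at -4.62 ± 0.16 and Il6 at -5.25 ± 0.21. The lowest value with S14 was that of Fst, which encodes the activin inhibitor follistatin: 0 reads with S14 and 20.8 ± 3.71 CPM with LPS, at least 130-fold lower.

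Between S14 and LPS at 3 h 5399 genes differed, 2775 higher and 2624 lower with S14. All 46 interferon-stimulated genes were lower with S14 (46 adjusted over the list alone, median -2.67, adjusted p = 8.45e-36), as were 19 of 24 cytokines and chemokines, with 1 higher (20 called adjusted over the list alone, median -2.7, adjusted p = 1.67e-12). All 19 genes of MHC class I and costimulation were lower as well (19 adjusted over the list alone, adjusted p = 1.67e-12), beside 4 of 5 dendritic cell markers (4 adjusted over the list alone, median -1.51, adjusted p = 0.0384, and adjusted p = 0.0957 with an estimated correlation). Of 20 antimicrobial effectors 10 were lower and 5 higher (16 called adjusted over the list alone, adjusted p = 0.042, and adjusted p = 0.434 with an estimated correlation). One of the higher ones was Marco, a scavenger receptor for bacteria, named here after its values were seen: 6.19 ± 1.55 CPM untreated, 52.7 ± 7.77 with S14 and 10.1 ± 2.76 with LPS (S14 against LPS 2.37 ± 0.33, adjusted p = 4.54e-06). Of 25 cholesterol genes 18 were higher with S14 and 1 lower (21 called adjusted over the list alone, median 0.83, adjusted p = 8.11e-06, and adjusted p = 0.162 with an estimated correlation). The largest values above LPS were those of Sesn1, a stress-induced regulator of mTORC1, at 4.23 ± 0.19, the receptor Cd300lb at 3.74 ± 0.14 and Tfeb at 3.71 ± 0.34. Scaled to spike-in reads, 2232 genes passed, 612 higher and 1620 lower, or 3479 with 1066 higher without untreated 18 h replicate 4.

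Across genes, the S14 and LPS changes at 3 h had a correlation of 0.741 (Spearman 0.648), above the 0.484 to 0.518 of 20 simulations with unchanged treated groups. Their covariance was 0.4893, against 0.0311 simulated and 0.4622 with separate controls. Of the 1786 genes S14 changed at 3 h, 1564 (87.6%) changed in the same direction with LPS, 946 up and 618 down. Independent lists would share 268.1 and 219.1. The simulations shared at most 1, but their treated groups were unchanged, so few calls were possible. They do not measure what shared controls add to the overlap of changed genes. With separate pairs of controls, which leave fewer control libraries per comparison, the mean overlap was 1078.7. Of the 1786 genes, another 64 (3.58%) changed in opposite directions, 35 of them up with S14. The following were chosen from these after their values were seen. Herpud1, a component of protein degradation at the endoplasmic reticulum, gave 0.85 ± 0.12 with S14 and -1.93 ± 0.14 with LPS. Nr1h3, which encodes LXRα, gave 0.5 ± 0.14 and -1.25 ± 0.16. Mertk, a receptor for apoptotic cells, gave -1.17 ± 0.26 with S14 and 2.41 ± 0.21 with LPS. Scaled to spike-in reads, the S14 calls of Herpud1, Nr1h3 and Mertk were lost, that of Nr1h3 also without untreated 18 h replicate 4. Outside these 64 genes, Siglece, an inhibitory sialic acid receptor also chosen after its values were seen, rose with S14 (2.38 ± 0.35, adjusted p = 8.9e-07). Siglece was not called with LPS (-0.45 ± 0.48, adjusted p = 0.447) and differed from LPS by 2.83 ± 0.38 (adjusted p = 3.2e-08).

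**Figure D3:**
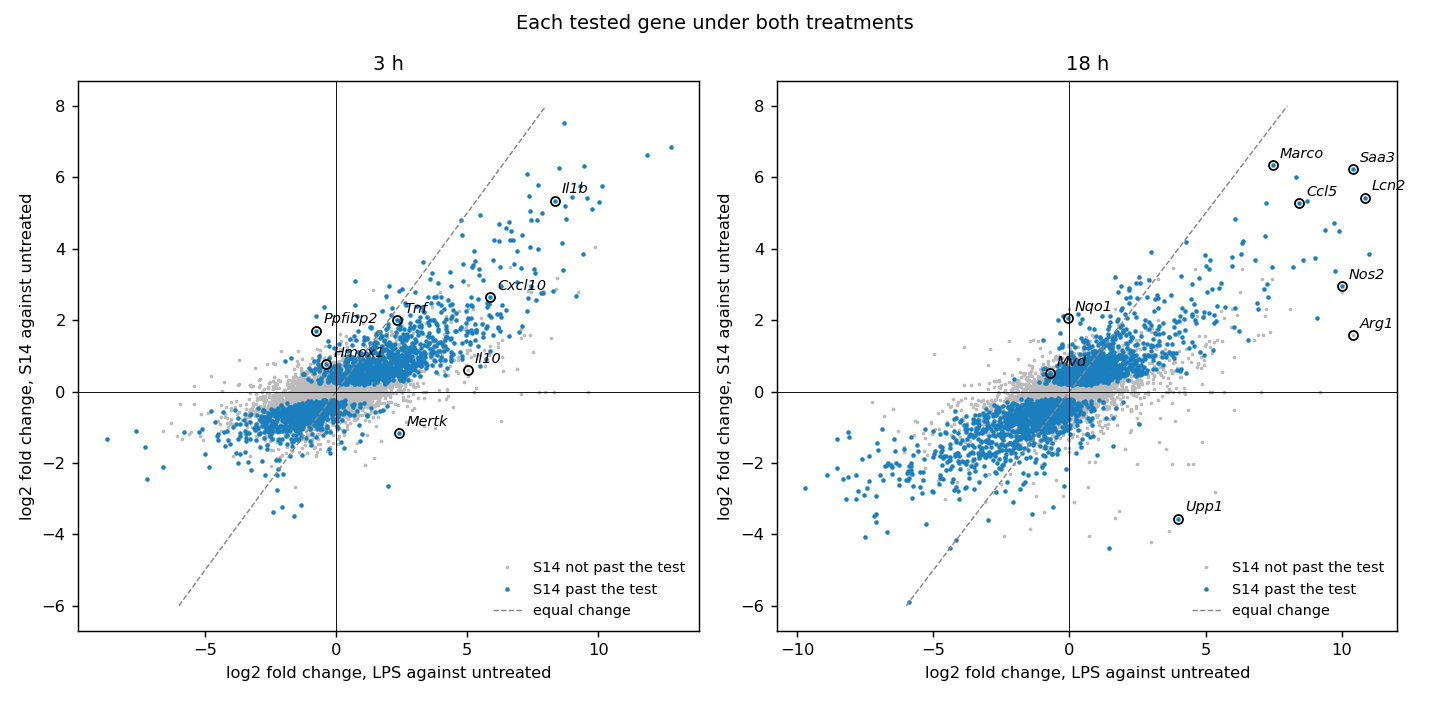
Log2 fold change of each tested gene with S14 (vertical) against that with LPS (horizontal) at 3 h and 18 h, with a dashed line of equal change and labelled genes. The correlation across genes is 0.741 at 3 h and 0.721 at 18 h, and most values lie nearer to 0 with S14.

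S14 against untreated cells at 18 h asks which changes were present late. Antimicrobial genes were high, fewer cytokines were high than at 3 h, and cell cycle genes were low. Marco rose from 1.54 ± 0.415 to 128 ± 31.5 CPM (6.34 ± 0.39, adjusted p = 2.19e-10), Saa3 from 40.4 ± 10.7 to 3050 ± 513 CPM (6.24 ± 0.2, adjusted p = 1.64e-15) and Ccl5 from 37.7 ± 7.68 to 1460 ± 91.2 CPM (5.28 ± 0.11, adjusted p = 1.16e-33). Hp, the haemoglobin-binding protein haptoglobin, and Slpi, a protease inhibitor of innate defence, rose by 4.35 ± 0.27 and 4.18 ± 0.39. Tnf was 18.4 ± 1.24 against 14.8 ± 1.53 CPM (0.32 ± 0.13, adjusted p = 0.0644; 0.38, adjusted p = 0.0436, without untreated replicate 3). It passed with a replicate block (0.33, adjusted p = 0.0375) and with limma on the deposited normalized values (0.31, adjusted p = 0.0262). Nlrp3 gave -0.55 ± 0.21 (adjusted p = 0.0527) and passed under other settings, such as DESeq2 (-0.57, adjusted p = 0.0172), and without untreated replicate 2 (-0.63, adjusted p = 0.0423). Cxcl10 was 83.3 ± 8.94 against 63 ± 26.7 CPM (0.41 ± 0.19, adjusted p = 0.136; 0.74, adjusted p = 4.71e-05, without untreated replicate 4). Il1b, at 13 ± 3.47 against 3.1 ± 1.65 CPM (2.06 ± 0.59, adjusted p = 0.0153), lost its call without untreated replicate 3 (1.8, adjusted p = 0.0505) or replicate 4 (2.17, adjusted p = 0.0503).

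S14 changed 2844 genes at 18 h, 1480 higher and 1364 lower; 281 rose and 424 fell by at least 2-fold. Of 20 antimicrobial effectors 17 rose (18 adjusted over the list alone, median 2.34, adjusted p = 5.3e-22; 1.65 and 1.64 scaled to spike-in reads). In the cell cycle list 29 of 32 fell (29 adjusted over the list alone, median -1.45, adjusted p = 3.57e-26; -2.44 and -1.96 scaled to spike-in reads). The mitotic genes Ube2c (105 ± 33.8 to 16.7 ± 2.42 CPM, -2.65 ± 0.18), Ccna2 (-2.5 ± 0.19) and Ccnb2 (-2.33 ± 0.18) were among them. The next lists rose relative to the typical gene, but when scaled to spike-in reads the sign of their medians depended on 1 library, negative with untreated replicate 4 and positive without it. Of 23 NRF2 genes 18 rose and 2 fell (20 called adjusted over the list alone, adjusted p = 2.12e-10; median 0.67, and -0.32 and 0.2 scaled to spike-in reads), including Nqo1, a quinone reductase, at 2.06 ± 0.3 and the peroxidase Prdx1 at 1.37 ± 0.14. Of 21 genes of the integrated stress response 13 rose and 1 fell (15 called adjusted over the list alone, adjusted p = 8.06e-08; median 0.8, and -0.34 and 0.25 scaled to spike-in reads), with Mthfd2, of mitochondrial folate metabolism, at 1.41 ± 0.13. Of 24 genes of glycolysis and hypoxia 15 rose (17 called adjusted over the list alone, adjusted p = 1.01e-07; median 0.57, and -0.46 and 0.05 scaled to spike-in reads).

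Cytokines and chemokines belong to these lists as well. Of 24 cytokines and chemokines 9 rose and 2 fell (14 called adjusted over the list alone, adjusted p = 3.64e-05), with a median of 0.84, or 0.5 with genes at 0 counts set to their bound, and -0.16 and 0.32 scaled to spike-in reads. Other medians were negative in both versions of that scaling. Of 30 genes of oxidative phosphorylation 15 rose (16 adjusted over the list alone, adjusted p = 1.79e-06; median 0.26, and -0.76 and -0.18 scaled to spike-in reads). Of 22 chaperones of the endoplasmic reticulum 11 rose and 1 fell (15 called adjusted over the list alone, adjusted p = 3.64e-05; median 0.32, and -0.72 and -0.15 scaled to spike-in reads). Of 46 interferon-stimulated genes 25 rose (27 adjusted over the list alone, adjusted p = 1.35e-09, and adjusted p = 0.12 with an estimated correlation; median 0.35, 0.38 with genes at their bound, -0.67 and -0.08 scaled to spike-in reads). Irf7, a transcription factor of the interferon response, rose from 498 ± 102 to 1010 ± 41 CPM (1.02 ± 0.11). Of 28 NF-kB regulators 13 rose and 1 fell (16 called adjusted over the list alone, adjusted p = 6.31e-05, and adjusted p = 0.114 with an estimated correlation; median 0.34, and -0.69 and -0.11 scaled to spike-in reads). Of 19 genes of MHC class I and costimulation 12 rose and 1 fell (13 called adjusted over the list alone, adjusted p = 1.69e-05, and adjusted p = 0.0756 with an estimated correlation; median 0.34, and -0.67 and -0.12 scaled to spike-in reads). Lysosome genes rose in 14 of 40 cases and fell in 4 (20 called adjusted over the list alone, adjusted p = 0.0126, and adjusted p = 0.321 with an estimated correlation; median 0.12, and -0.85 and -0.39 scaled to spike-in reads).

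Genes of lipid handling moved both ways with S14 at 18 h relative to the typical gene, with negative medians when scaled to spike-in reads. With that scaling no LXR target was called higher, with or without untreated replicate 4. Of 17 LXR targets 5 rose and 2 fell (7 called adjusted over the list alone, adjusted p = 0.111; median 0.13, and -0.85 and -0.27 scaled to spike-in reads), with Nr1h3 at 1 ± 0.13 and Abca1 at 0.48 ± 0.13 (adjusted p = 0.00474). In the list of lipid droplets and fatty acid metabolism 6 of 27 rose and 7 fell (13 called adjusted over the list alone, adjusted p = 0.872; median -0.05, and -0.98 and -0.53 scaled to spike-in reads), with the acyl-CoA synthetase Acsl1 at 1.54 ± 0.13. Fabp5, a fatty acid carrier at 1.3 ± 0.15, is uncertain because its reads differ by 16.1% between the authors' tables. In the list of sphingolipid metabolism 3 of 35 rose and 8 fell (15 called adjusted over the list alone, adjusted p = 0.224; median -0.1, and -1.12 and -0.55 scaled to spike-in reads), with Ugcg, the glucosylceramide synthase, at -0.71 ± 0.17. Of 25 cholesterol genes 1 rose and 6 fell (8 called adjusted over the list alone, adjusted p = 0.111; median -0.25, and -1.17 and -0.62 scaled to spike-in reads), with Sqle, the squalene epoxidase, at -0.62 ± 0.17. Psap, the precursor of the saposins that aid sphingolipid breakdown, rose from 542 ± 250 to 1980 ± 223 CPM (1.87 ± 0.37, adjusted p = 0.000963). Among 24 macrophage identity genes 9 rose and 4 fell (14 called adjusted over the list alone, adjusted p = 0.111; median 0.17, and -0.87 and -0.32 scaled to spike-in reads), with Cx3cr1 down from 148 ± 89.7 to 42.4 ± 12.3 CPM (-1.8 ± 0.32). When scaled to spike-in reads 7639 genes passed, 106 higher and 7533 lower, or 2291 with 130 higher without untreated replicate 4.

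LPS against untreated cells at 18 h gives the late reference. LPS changed 6517 genes, 3200 higher and 3317 lower, and 1243 rose and 1553 fell by at least 2-fold. Saa3 reached 55200 ± 5380 CPM (10.42 ± 0.23, adjusted p = 1.13e-19), Il1b 1700 ± 867 CPM (9.09 ± 0.47, adjusted p = 1.88e-12) and Nos2 405 ± 41.7 CPM (10 ± 0.27, adjusted p = 2.81e-22). Tnf was 89.5 ± 11.4 CPM (2.59 ± 0.11, adjusted p = 3.41e-23). Arg1, which encodes the arginine-degrading enzyme arginase-1, had 0 untreated reads and 36.6 ± 10.7 CPM with LPS, at least 297-fold higher. Timp1, an inhibitor of metalloproteinases, reached 225 ± 28.3 CPM over 2 untreated reads, a ratio of 2730 (755 to 22500). The mitotic cyclin gene Ccna2 fell from 42.3 ± 7.29 to 0.221 ± 0.255 CPM (-7.36 ± 0.35), and Ighm, the immunoglobulin µ chain, from 132 ± 32 to 0.584 ± 0.435 CPM (-7.77 ± 0.29).

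Inflammatory, antimicrobial, glycolytic and antioxidant genes were high with LPS at 18 h, and cholesterol, cell cycle and MHC class II genes were low. Of 24 cytokines and chemokines 22 rose and 1 fell (23 called adjusted over the list alone, median 2.95, adjusted p = 4.36e-13), and all 46 interferon-stimulated genes rose (46 adjusted over the list alone, median 1.69, adjusted p = 8.28e-22). Of 20 antimicrobial effectors 19 rose (19 adjusted over the list alone, median 5.22, adjusted p = 8.23e-15), and of 24 genes of glycolysis and hypoxia 23 rose (23 adjusted over the list alone, median 1.76, adjusted p = 1.39e-14), with the lactate transporter Slc16a3 at 4.08 ± 0.11. Of 23 NRF2 genes 20 rose (20 adjusted over the list alone, median 1.29, adjusted p = 2.79e-10), with the heme-degrading enzyme Hmox1 from 233 ± 62.7 to 3000 ± 266 CPM (3.69 ± 0.15). Of 25 cholesterol genes 23 fell (24 adjusted over the list alone, median -1.68, adjusted p = 9.23e-11). In the cell cycle list 28 of 32 fell and 2 rose (30 called adjusted over the list alone, median -3.12, adjusted p = 6.25e-18). All 7 MHC class II genes fell (7 adjusted over the list alone, median -2.23, adjusted p = 2.7e-05), with their transactivator Ciita at -4.68 ± 0.32. These 8 list medians kept their sign with spike-in scaling, with and without untreated replicate 4.

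LPS changed further lists at 18 h. Of 28 NF-kB regulators 24 rose and 1 fell (25 called adjusted over the list alone, adjusted p = 3.31e-14), of 19 genes of MHC class I and costimulation 18 rose (18 adjusted over the list alone, adjusted p = 2.06e-09), and of 21 genes of the integrated stress response 14 rose and 2 fell (16 called adjusted over the list alone, adjusted p = 2.28e-05). Of 22 chaperones of the endoplasmic reticulum 14 rose and 2 fell (16 called adjusted over the list alone, adjusted p = 0.00132; median 0.42, and -0.21 and 0.33 scaled to spike-in reads). In the inflammasome list 11 of 19 rose and 4 fell (15 called adjusted over the list alone, adjusted p = 0.00176; median 0.57, and -0.25 and 0.67 scaled to spike-in reads), while Nlrp3 gave 0.36 ± 0.19 (adjusted p = 0.113), and passed without LPS replicate 2 (0.49, adjusted p = 0.0373), with a replicate block (0.35, adjusted p = 0.0307) and with no filter on low counts (0.38, adjusted p = 0.0185). Of 18 genes of alternative activation, the programme linked to interleukin-4, 4 rose and 11 fell (15 called adjusted over the list alone, adjusted p = 0.0853). The C-type lectin receptor Clec10a of that list fell by 5.82 (SE 0.22). Of 21 immediate early genes 9 rose and 9 fell (18 called adjusted over the list alone), with a median of -0.67, a mean of -0.44 and a list test pointing up (adjusted p = 0.578). With spike-in scaling 5221 genes passed, 695 higher and 4526 lower, or 3985 with 1431 higher without untreated replicate 4.

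**Figure D4:**
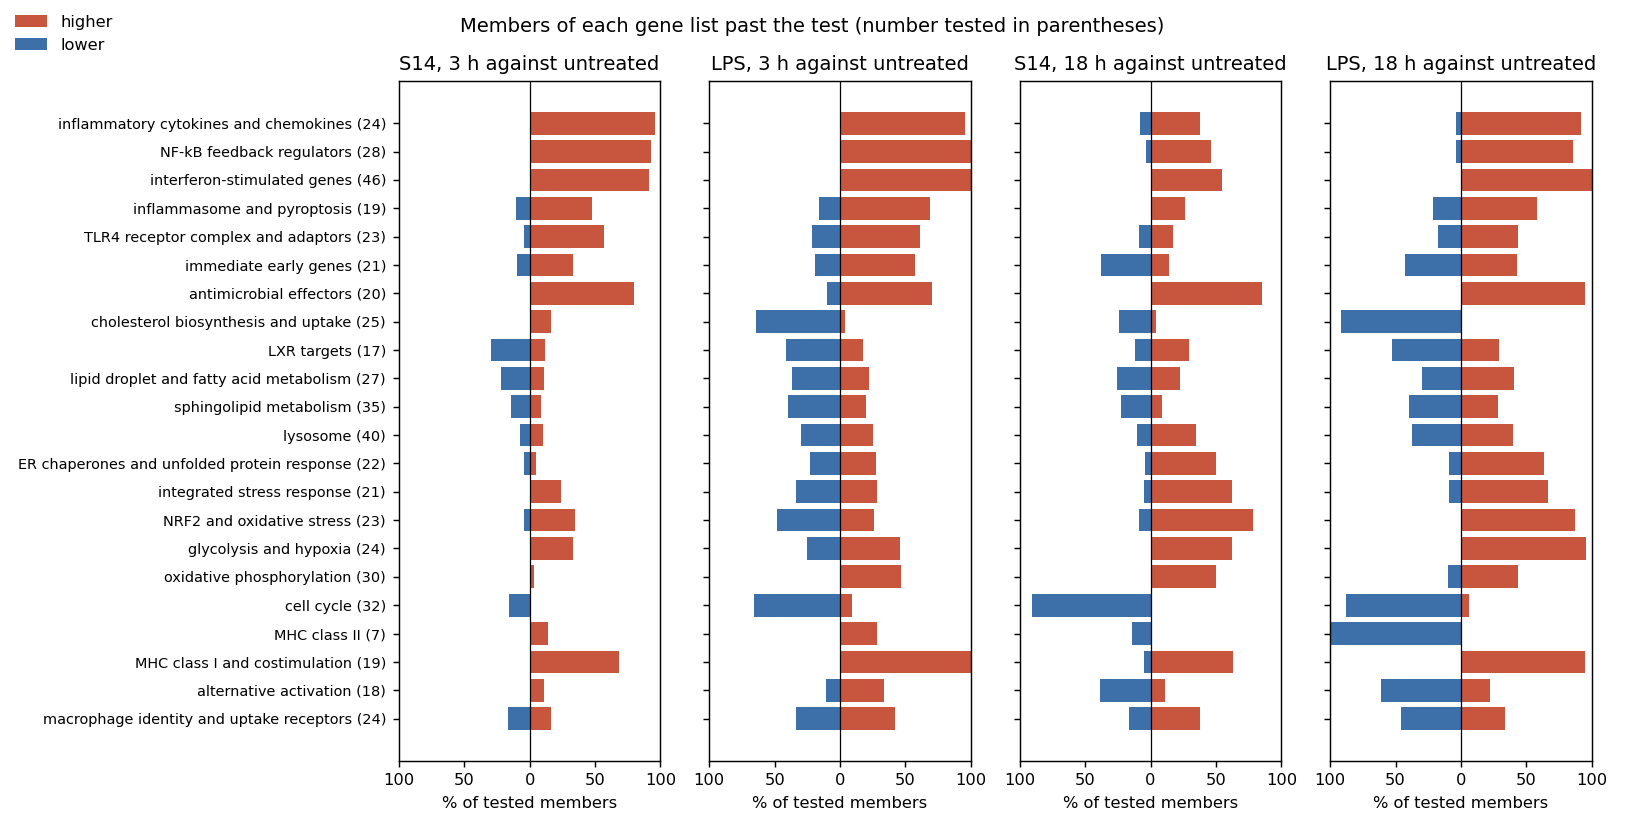
Percent of the tested members of each gene list that passed the gene test, higher or lower than untreated cells, for S14 and LPS at 3 h and 18 h. At 3 h 42 of 46 interferon-stimulated genes rose with S14 and 46 with LPS; at 18 h 29 of 32 cell cycle genes fell with S14 and 28 with LPS. Bars give directions relative to the typical gene; scaled to spike-in reads, the S14 medians at 18 h stay positive for antimicrobial genes and negative for cell cycle genes. Those of cytokines, NRF2 and glycolysis turn negative, but are 0.32, 0.2 and 0.05 without untreated replicate 4; for interferon-stimulated genes they are -0.67 and -0.08.

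The direct comparison of S14 with LPS at 18 h found 4996 genes, 2496 higher and 2500 lower with S14. Il1b was lower by a log2 fold change of -7.03 ± 0.41, Nos2 by -7.05 ± 0.21 and Tnf by -2.28 ± 0.11. Nlrp3 was lower at -0.92 ± 0.21 (adjusted p = 0.000718) and Tlr4 higher at 0.41 ± 0.1 (adjusted p = 0.00143). Scaled to spike-in reads, Tlr4 was not called higher, with or without untreated 18 h replicate 4. Timp1 was lower at -7.17 ± 0.29, and Rasgrp3 and Clec10a were higher at 5.82 ± 0.31 and 4.56 ± 0.24. Of 25 cholesterol genes 22 were higher with S14 (22 adjusted over the list alone, median 1.39, adjusted p = 5.8e-13), as were all 7 MHC class II genes (7 adjusted over the list alone, median 1.62, adjusted p = 1.51e-06). In the cell cycle list 26 of 32 were higher and 3 lower (29 called adjusted over the list alone, median 1.92, adjusted p = 9.71e-14). Lower with S14 were 22 of 24 genes of glycolysis and hypoxia (22 adjusted over the list alone, median -1.14, adjusted p = 2.89e-15), 43 of 46 interferon-stimulated genes (43 adjusted over the list alone, median -1.25, adjusted p = 1.5e-22) and 14 of 20 antimicrobial effectors, with 1 higher (15 called adjusted over the list alone, median -2.88, adjusted p = 1.19e-09). Beside these groups, 3 of 4 stromal and endothelial markers were lower (3 adjusted over the list alone, median -2.24, adjusted p = 0.0151), as were all 3 erythroid and megakaryocyte markers (3 adjusted over the list alone, median -2.34, adjusted p = 0.0319, and adjusted p = 0.101 with an estimated correlation). Higher were 6 of 8 mitochondrial transcripts (6 adjusted over the list alone, median 0.43, and 0.03 in both versions scaled to spike-in reads; adjusted p = 0.047, and adjusted p = 0.325 with an estimated correlation) and the B cell marker Ighm (list median 4.99, adjusted p = 0.0274). Slpi, at 20.6 ± 3.8 and 21.9 ± 3.73 CPM, did not pass (-0.09 ± 0.29, adjusted p = 0.826; named here after its values were seen). Under spike-in scaling 1915 genes passed, 519 higher and 1396 lower, or 3679 with 867 higher when untreated 18 h replicate 4 was left out of the fit.

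The responses at 18 h had a correlation across genes of 0.721 (Spearman 0.654), against 0.457 to 0.492 in 20 simulations, and a covariance of 0.4639, against 0.0281 simulated and 0.4128 with separate controls. The simulated values are too low at 18 h, since the observed spread of the untreated libraries alone gives an expected covariance of 0.0513. Of the 2844 genes S14 changed, 2274 (80%) changed in the same direction with LPS, 1169 up and 1105 down, where independent lists would share 404.2 and 386.1. Another 88 (3.09%) changed in opposite directions. Chosen from these after their values were seen, Dusp6 and Spry2, inhibitors of ERK signalling, gave -0.75 ± 0.16 and -1.19 ± 0.24 with S14 and 0.67 ± 0.15 and 0.63 ± 0.21 with LPS. Mt2 gave -0.75 ± 0.12 and 1.36 ± 0.11. Nqo1 differed between the treatments by 2.12 ± 0.32 (adjusted p = 3.78e-07) and gave -0.07 ± 0.34 with LPS (adjusted p = 0.883). Scaled to spike-in reads, the genes changed in the same direction numbered 4110, 95 up and 4015 down, or 1421 without untreated replicate 4.

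The S14 effect was compared between 18 h and 3 h, asking which parts of it faded or grew. It differed for 1944 genes, 892 upward and 1052 downward. The effect on Tnf fell by 1.68 (SE 0.16, adjusted p = 7.33e-11), on Nlrp3 by 2.19 (SE 0.26, adjusted p = 7.28e-07) and on Cxcl10 by 2.24 (SE 0.26, adjusted p = 3.87e-06). For Il1b the value of -3.29 ± 0.82 (adjusted p = 0.00845) lost its call without untreated 18 h replicate 2 (-2.93, adjusted p = 0.0508) or replicate 4 (-3.18, adjusted p = 0.0582). The effect grew for Marco (3.25 ± 0.62), Slpi (3.49 ± 0.67) and the chemokine gene Ccl8 (2.82 ± 0.7, adjusted p = 0.00351). It fell for the chemokine gene Cxcl1 (-4.44 ± 0.79) and for Il4i1, an amino acid oxidase (-3.94 ± 0.53). The effect was lower at 18 h for 12 of 24 cytokines and chemokines (12 adjusted over the list alone, median -1.8, adjusted p = 1.15e-17) and 21 of 32 cell cycle genes (26 called adjusted over the list alone, median -1.23, adjusted p = 6.94e-15), beside the B cell marker Ighm (list median -2.88, adjusted p = 0.0129, and adjusted p = 0.0501 with an estimated correlation). It was higher for 14 of 23 NRF2 genes and lower for 4 (18 called adjusted over the list alone, adjusted p = 0.000208, and adjusted p = 0.0729 with an estimated correlation), with a median of 0.61, and -0.48 and -0.02 scaled to spike-in reads. Scaled so, 4115 genes passed, 20 upward and 4095 downward, or 1416 with 25 upward without untreated 18 h replicate 4.

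The LPS effect differed between 18 h and 3 h for 6000 genes, 2943 upward and 3057 downward. The effect on Il10 fell by 4.67 (SE 0.33, adjusted p = 3.79e-14), on Cxcl10 by 1.82 (SE 0.25) and on Nlrp3 by 1.2 (SE 0.25). The fitted value of Arg1 was 12.83 ± 2.47 (adjusted p = 4.07e-05); with groups at 0 reads it depends on the prior count and is no bound. The effect grew for Marco (6.75 ± 0.66) and Slamf6, a receptor of the SLAM family (6.5 ± 1.07). It was lower at 18 h for 38 of 46 interferon-stimulated genes (39 adjusted over the list alone, median -1.99, adjusted p = 9.42e-18). It was higher for 19 of 24 genes of glycolysis and hypoxia and lower for 2 (22 called adjusted over the list alone, median 1.8, adjusted p = 7.92e-08), and for 19 of 23 NRF2 genes with 2 lower (21 called adjusted over the list alone, median 1.49, adjusted p = 3.77e-07). Antimicrobial effectors had 13 of 20 higher and 2 lower (15 called adjusted over the list alone, median 2.22, adjusted p = 0.000444, and adjusted p = 0.112 with an estimated correlation). Beside these, 5 of 8 mitochondrial transcripts were lower (6 called adjusted over the list alone, median -0.98, adjusted p = 0.00922, and adjusted p = 0.239 with an estimated correlation), as was Ighm (list median -7.61, adjusted p = 0.0374, and adjusted p = 0.112 with an estimated correlation). Scaled to spike-in reads the medians of the 4 pathway lists kept their sign, with and without untreated 18 h replicate 4. Of all genes 4857 passed, 381 upward and 4476 downward, or 4233 with 850 upward without it.

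Untreated cells at 18 h differed from those at 3 h in 4547 genes, 2249 higher and 2298 lower; time in culture and handling before 3 h are not separated here. Tnf fell from 175 ± 17.8 to 14.8 ± 1.53 CPM (-3.56 ± 0.11, adjusted p = 4.91e-27), Nlrp3 from 57.8 ± 19.4 to 20.4 ± 2.34 CPM (-1.49 ± 0.18, adjusted p = 1.57e-07) and Cxcl10 from 277 ± 24.2 to 63 ± 26.7 CPM (-2.14 ± 0.19, adjusted p = 1.62e-08). The chemokine gene Cxcl2 fell by 4.43 (SE 0.19) and Gpr84, a receptor for medium-chain fatty acids, by 4.87 (SE 0.32). Abca1 rose from 41.4 ± 1.42 to 81.8 ± 10.4 CPM (0.98 ± 0.14). Of 24 cytokines and chemokines 12 fell and 1 rose (13 called adjusted over the list alone, median -1.57, or -0.93 with genes at their bound, and -0.95 and -1.29 scaled to spike-in reads; adjusted p = 2.22e-05). Of 28 NF-kB regulators 21 fell (22 adjusted over the list alone, median -0.86, and 0 and -0.58 scaled to spike-in reads; adjusted p = 1.89e-11), of 24 glycolysis genes 19 fell and 1 rose (21 called adjusted over the list alone, median -0.87, and -0.04 and -0.59 scaled to spike-in reads; adjusted p = 2.76e-11), and of 23 NRF2 genes 18 fell (18 adjusted over the list alone, median -0.72, and 0.19 and -0.39 scaled to spike-in reads; adjusted p = 1.72e-08).

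Antigen presentation and macrophage identity genes rose in untreated cells over time, and their medians stayed positive when scaled to spike-in reads, with and without untreated 18 h replicate 4. All 7 MHC class II genes rose (7 adjusted over the list alone, median 1.61, adjusted p = 5.46e-09). Beside them, 2 of 5 dendritic cell markers rose (2 adjusted over the list alone, median 1.53, 0.69 with genes at their bound, and 2.36 and 1.39 scaled to spike-in reads; adjusted p = 0.164), as did 3 of 7 osteoclast markers (3 adjusted over the list alone, median 0.46, adjusted p = 0.31) and the B cell marker Ighm (1.79 ± 0.16). Rises held for 18 of 24 genes of macrophage identity and uptake, with 2 lower (20 called adjusted over the list alone, median 0.61, adjusted p = 3.08e-08). Of 46 interferon-stimulated genes 27 rose and 2 fell (31 called adjusted over the list alone, median 0.59, or 0.51 with genes at their bound, adjusted p = 7.41e-08, and adjusted p = 0.176 with an estimated correlation). Of 40 lysosome genes 22 rose and 2 fell (24 called adjusted over the list alone, adjusted p = 3.96e-05, and adjusted p = 0.155 with an estimated correlation). Of 35 genes of sphingolipid metabolism 15 rose and 2 fell (19 called adjusted over the list alone, adjusted p = 0.00671). Of 32 cell cycle genes 26 fell (27 adjusted over the list alone, median -0.77, and 0.11 and -0.48 scaled to spike-in reads; adjusted p = 3.08e-08). Scaled to spike-in reads, 5639 genes passed, 5426 higher and 213 lower, or 2426 with 2057 higher without untreated 18 h replicate 4.

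Markers of other cell types were few and mostly low. Of 13 B cell markers 1 was tested, Ighm, at 38 CPM untreated and 40.7 with S14 at 3 h; at 18 h it was 132 ± 32 CPM untreated, 19.2 ± 4.77 with S14 (-2.78 ± 0.17, adjusted p = 2.42e-15) and 0.584 ± 0.435 with LPS. With S14 at 18 h, beside the antimicrobial genes, 3 of 4 neutrophil markers rose (3 adjusted over the list alone, adjusted p = 0.0093, and adjusted p = 0.0731 with an estimated correlation). With it 1 of 3 erythroid and megakaryocyte markers rose, the platelet chemokine gene Pf4 (1.53 ± 0.1; list adjusted p = 0.0231, and adjusted p = 0.104 with an estimated correlation), which macrophages also express. With LPS at 18 h all 4 stromal and endothelial markers rose (4 adjusted over the list alone, median 4.19, adjusted p = 0.00541), as did all 3 erythroid and megakaryocyte markers (adjusted p = 0.0127, and adjusted p = 0.0543 with an estimated correlation) and 3 of 4 neutrophil markers (adjusted p = 0.0243, and adjusted p = 0.0852 with an estimated correlation). With LPS at 3 h 3 of 5 dendritic cell markers rose (3 adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.0711 with an estimated correlation). With LPS at 18 h the osteoclast markers had 2 of 7 higher and 3 lower (adjusted p = 0.495), the T and NK cell markers 1 of 3 lower (adjusted p = 0.701), and the 1 tested mast cell and basophil marker was lower (list adjusted p = 0.495). Of 8 mitochondrial transcripts, a sign of RNA quality, 6 were lower and 1 higher with LPS at 18 h (7 called adjusted over the list alone, median -0.81, adjusted p = 0.0251, and adjusted p = 0.318 with an estimated correlation), beside the fall in cell cycle genes, and 3 were lower with S14 at 18 h (adjusted p = 0.111).

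Of the 279 list tests over 9 comparisons, 132 passed with the preset correlation and 78 with an estimated one. The list calls given without a second p hold with an estimated correlation.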

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

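Tests chosen only after their result was seen are the swap test of replicate 4 below, all 3 tests of the shared S14 and LPS response and both tests of the untreated time difference.

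The untreated 18 h library of replicate 4 stood far from its group, with a spread of log2 deviations of 0.429 against 0.202 to 0.24, and a pseudogene share of 1.01% against 1.52% to 1.61%. A library of another group under this label is argued against, since it correlated at 0.956 with the mean of its own group and at 0.795 to 0.93 with the other groups. RNA from other cell types cannot be told apart, as the dendritic cell list deviated by a median of 1.05 but only 3 of its 5 tested markers lay above the other 3 libraries of its group. A library preparation that differed between libraries fits: over 20 libraries of the other groups, the spike-in share and the lean along this library had a Spearman rho of -0.586 (permutation p = 0.0246), or -0.434 without the 2 farthest, for which no p was computed. The same lean had a rho of -0.829 with the pseudogene share, -0.296 with the rRNA share, -0.051 with genes detected and 0.203 with gene counts. As the amount of spike-in added is not given, its share alone cannot single out preparation. A differing preparation stays open, and no biological explanation other than RNA from other cell types was tested.

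S14 and LPS moved genes in the same direction at 3 h, LPS by more. Untreated libraries shared by both comparisons are argued against as the whole source, with a covariance of 0.4893 against 0.0311 simulated. The LPS response scaled down by 1 factor is argued against, since the median ratio of S14 to LPS changes was 0.655 ± 0.0624 (SE) for antimicrobial effectors and 0.272 ± 0.102 for the inflammasome list. These are the highest and lowest of 8 lists, 3.2 standard errors apart (p = 0.0381 adjusted over all pairs of lists, permutation p of the range 0.0019). Both p-values and the standard errors take the genes of a list as independent, which they are not, so 1 factor is not excluded. A trace of LPS in the S14 cultures cannot be told apart, because no group received less LPS: 3.58% of the S14 genes changed in the opposite direction with LPS, of 1060 genes that S14 raised 111 were higher with S14 than with LPS, and a response to S14 itself stays open, not tested here.

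Inflammatory genes were higher in untreated cells at 3 h than at 18 h, in 33 of 52 tested genes. Reads carried over from the LPS 3 h libraries would raise every gene by the same share of its LPS level. The test took 47 genes with at least 100 CPM with LPS at 3 h and at least 64 times their untreated 18 h level. At 3 h untreated cells exceeded that level by a median of 0.363% of the LPS level (SE 0.187). The 33 genes need 0.232% to 38.2%, with a median of 4.67%. This argues against carried-over reads as the source for the genes at or above that median need. For the genes below it, carried-over reads cannot be told apart. Scaling of the libraries between times cannot alter the median of -1.07 relative to all genes. For a fall in the genes themselves it cannot be told apart: scaled to spike-in reads, whose added amount is not given in the sources used here, the median of the 52 genes was -0.23 (SE 0.238), or -0.69 (SE 0.252) without untreated 18 h replicate 4. With that scaling 15 of the 52 genes were called lower and 9 higher at 18 h, or 21 and 3 without that library. Time in culture and handling of the cells before 3 h were not tested and stay open.

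The S14 effect differed between 18 h and 3 h for 1944 genes, tested as an interaction. Other splits of the same libraries called as many in 6 of 100 cases, the real one included, and at most 3747, so this count does not exclude a chance division of the libraries. Nor does it test chance alone, since the libraries divided anew differ by time. Of those 6, 5 were among the 31 splits that keep most, not all, libraries of each treatment sorted by time. A treatment with its times reversed counts as sorted here. The highest of the other splits called 1972. Among index genes the effect differed for Tnf (-1.68), Nlrp3 (-2.19), Cxcl10 (-2.24) and Tlr4 (0.54). Scaled to spike-in reads, the effect on Tlr4 was not called higher at 18 h, with or without untreated 18 h replicate 4. For Il1b the effect differed by -3.29, a call lost without untreated 18 h replicate 2 (-2.93, adjusted p = 0.0508) or replicate 4 (-3.18, adjusted p = 0.0582).

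The LPS effect differed between the times for 6000 genes. Of 100 splits 2 called as many as the real one, the real one included (5657 in a fit of these libraries alone, highest other 6812). Both were among the 22 splits mostly sorted by time in the same sense, and the highest of the others called 4752. The effect differed for Il10 (-4.67), Nlrp3 (-1.2), Cxcl10 (-1.82) and Arg1 (12.83, a fitted value that depends on the prior count). For Tlr4 it was -0.43, a call lost without LPS 3 h replicate 3 (-0.34, adjusted p = 0.0526).

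In the group comparisons, fitted on their own libraries, only 1 of 35 splits, the real one, called as many genes, and the other splits called at most 0 by the edgeR test. Each other split puts libraries of both groups on both sides, which widens the spread within a side. Few calls were therefore likely there, and the splits do not measure chance calls among like libraries. The real counts were 2421 for S14 at 3 h, 6711 for LPS at 3 h, 2090 for S14 at 18 h and 5536 for LPS at 18 h. They were 5573 for S14 against LPS at 3 h, 5346 at 18 h and 3697 for untreated cells over time.

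Relative to the range of their group, single libraries lay apart in 13 of 127 tests of the farthest value. So many tests give some such values by chance. In 5 of the 13 only 1 library of the group had reads, which alone gives that result. The TMM factor of untreated 3 h replicate 3 was 1.182, against 1.176 to 1.177. The spike-in share of S14 3 h replicate 4 was 0.0356%, against 0.0457% to 0.0472%. Il6 was at 0.2252 CPM in untreated 3 h replicate 2 and 0.1993 in S14 18 h replicate 1, and at 0 in the others of those groups. Il10 was at 12.23 CPM in S14 3 h replicate 2, against 7.588 to 8.307. Cxcl10 was at 240.9 CPM in untreated 3 h replicate 1, against 285.3 to 293.9. Ifnb1 was at 2.319 CPM in S14 3 h replicate 3, against 0 to 0.3391, and at 0.3871 in untreated 18 h replicate 1, against 0. Arg1 was at 0.1695 CPM in S14 3 h replicate 4 and 0.1993 in S14 18 h replicate 1, and at 0 in the others. Abca1 was at 72.93 CPM in S14 3 h replicate 3, against 56.96 to 58.57.

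Reads of the 92 ERCC and 22 SIRV spike-in sequences, which the main comparisons do not use, were present in every library, at least 705.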

How the results depend on the processing

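Alternatives chosen only after the data were seen are the recovered reads, the scaling to spike-in reads, that scaling without untreated 18 h replicate 4, and the left-out libraries of overlaps and correlations. Apart from spike-in scaling, counts of changed genes and overlaps stayed within 1.5 times their value under the alternatives run, with split controls taken as the mean of 6 assignments. The lowest of these had an 18 h overlap of 1294, against 2274 as reported and a mean of 1606.8.

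Leaving out 1 library gave 1493 to 1650 genes for S14 at 3 h, 6071 to 6230 for LPS at 3 h, 2326 to 3081 for S14 at 18 h and 6018 to 6447 for LPS at 18 h. For S14 against LPS it gave 4932 to 5093 at 3 h and 4527 to 4836 at 18 h. The S14 and LPS effects differed between times for 1648 to 2118 and 5744 to 6121 genes, and untreated cells for 3960 to 4463. The overlaps ran from 1337 to 1563 and from 1899 to 2443, the correlations from 0.725 to 0.743 and from 0.704 to 0.729.

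Scaled to spike-in reads, 374 genes passed for S14 and 3296 for LPS at 3 h, 7639 for S14 at 18 h, and 4115 for the S14 effect over time. For S14 against LPS 2232 passed at 3 h and 1915 at 18 h, and the overlaps were 359 and 4110. Without untreated 18 h replicate 4 these were 795, 4671, 2291, 1416, 3479 and 3679, and 744 and 1421. The cause was not tested. The correlation of 0.741 at 3 h was 0.662 with split controls and 0.802 over genes with a mean log2 CPM of at least 5. At 18 h 0.721 became 0.589 with split controls. Of 279 list tests 132 passed, against 78 with an estimated correlation in place of the preset one. With fry 223 passed. Fry asks whether the members move on balance and not whether they differ from all other genes, so its count answers another question.

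Directions reversed for the NRF2 list with LPS at 3 h under fry (adjusted p = 0.000555), whose median was -0.21 and mean 0.04, and for genes that were not called. Without 1 library, the S14 effect over time ran from -0.45 to 0.08 for Il10, also 0.01 and 0.04, and from -0.14 to 0.01 for Abca1. The LPS effect over time ran from -0.16 to 0.86 for Nos2, also -0.03 and -0.11. For S14 against LPS, Il10 ran from -0.05 to 0.23 at 18 h and Arg1 from 0 to 1.86 at 3 h. For S14 at 18 h, Il6 and Arg1 ran from 0 to 1.87 and Ifnb1 from -2.4 to 0. For S14 at 18 h, Apoe ran from -0.01 to 0.16, and for LPS at 18 h Nqo1 from -0.32 to 0.09 and Chchd10 from -0.04 to 0.11. Slpi ran from -0.18 to 0.02 for S14 against LPS at 18 h, and Nqo1 was 0.05 with LPS at 18 h by limma on the deposited normalized values. In untreated cells over time Il6 ran from -1.98 to 0 and Ifnb1 from 0 to 2.4. Il6, Arg1 and Ifnb1 rest there on at most 3 reads in 1 group, and leaving out a library with those reads leaves none; for the others the cause was not tested.

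No label says that the replicate numbers pair the libraries. Deviations of same-numbered libraries had a median correlation of 0.0265, 1 of 60 over 0.1, against -0.008 for other numbers, and 14 of 24 libraries correlated best with their own number, a hint from the data and not the design. A block by number gave 1863 genes for S14 at 3 h and 2948 at 18 h. Reads recovered from the normalized table gave 1789 and 2754.

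Of 7290 values of named genes under the alternatives, 7162 kept their direction and their side of the threshold, 59 lost their call, 47 gained one and 22 reversed. In simulated counts with the depths and spread of these libraries 55.2% of genes changed 1.5-fold were recovered for S14 at 3 h and 90.9% of those changed by a fold of 4.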

Other observations

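The genes of this part were chosen after their values were seen; their tests are those of the planned comparisons. Ptgs2, the inducible cyclooxygenase that starts prostaglandin synthesis, rose at 3 h by 3.99 ± 0.17 with S14 (adjusted p = 2.48e-18) and by 7.7 ± 0.17 with LPS. Gpr84, the receptor for medium-chain fatty acids, rose by 1.68 ± 0.21 and 1.59 ± 0.21. Ets2, a transcription factor of the ERK pathway, rose with S14 (1.23 ± 0.11, adjusted p = 3.98e-11) and differed from LPS by 1.33 ± 0.11 (adjusted p = 1.17e-12). Bach1, a repressor of antioxidant genes, fell with S14 (-0.53 ± 0.12, adjusted p = 0.000745) and rose with LPS (1.8 ± 0.11, adjusted p = 2.47e-18).

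At 18 h Chchd10, a mitochondrial protein gene, rose with S14 from 45.5 ± 6.26 to 97.8 ± 7.64 CPM (1.1 ± 0.12, adjusted p = 8.87e-10) and did not pass with LPS (0.05 ± 0.12, adjusted p = 0.759). Apoe, an apolipoprotein that accepts exported cholesterol, fell with LPS (-1.45 ± 0.11, adjusted p = 1.32e-12) and did not pass with S14 (0.08 ± 0.11, adjusted p = 0.661). With spike-in scaling the median shift of the 18 h values is -0.97 with S14 and -0.64 with LPS, or -0.48 and -0.16 without untreated replicate 4.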
